A study of Mus musculus with 8 samples.

How the data were processed

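Total RNA was measured in CD3-positive T cells taken from xenografts at day 30, on 8 whole-transcript arrays with biotin label. The mice were wild-type CD1, an outbred strain, and the grafts were tissues derived from human embryonic stem cells. In 4 samples the host was untreated and the graft was being rejected, and in 4 samples the host had been tolerised with antibodies against CD4, CD8 and CD40L. RNA was extracted with a column kit, per the labels' protocols. The labels number the samples 1 to 4 within each group and do not say that each sample came from a separate mouse, so p-values here measure only the spread between these samples, which may be technical.

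The deposited table holds log2 expression values for 35556 probe sets on 8 arrays, which the authors made with Affymetrix Expression Console and RMA, per the submitters' processing notes. RMA corrects background, equalises the distribution of probe intensities between arrays and summarises the probes of a probe set. The version of the software and the library files are not given in the sources used here. The base of the logarithm is not stated in the sources used here either. Base 2 was taken because the highest values, between 12.57 and 12.68, would lie beyond the range of the scanner on a natural or base-10 scale. Array medians lay between 0.468 and 0.521.

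Gene names came from the platform annotation given for these probes, updated through Entrez identifiers to the GRCm38.p6 gene table. Of the probe sets, 21218 had exactly 1 gene symbol, 1881 had several and 12457 had none listed. The 21218 probe sets with 1 symbol stood for 18820 genes, of which 1386 had several probe sets. Where a gene had several, the probe set with the highest mean over the 8 arrays represented it, and no gene was named from a probe set with several symbols. The build behind the probe design is not given in the sources used here, so no coordinates are printed.

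The test of single probe sets was limma's linear model with empirical Bayes moderation, without trend, tolerant minus rejecting, 2-sided, with Benjamini-Hochberg adjustment over the 21218 probe sets and a threshold of 0.05. Gene lists were tested with limma's camera, a competitive test of whether a list's genes shift relative to the other genes, at a preset inter-gene correlation of 0.01, 2-sided and adjusted over the lists. The design, the alternatives, the rule for named genes and 49 gene lists were fixed before the data were examined. The lists comprised 30 gene programmes, 18 sets of markers of other cell types and 1 set of sex-linked genes. They held 833 genes, of which 738 were matched and 95 had no probe set with a single symbol. Lists with at least 5 measured members were tested, which left 48. R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

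Genes were named by 3 criteria. The first took probe sets with an adjusted p under 0.05 and no overlap between the groups, the 12 with the largest difference in each direction. Where fewer passed, those with the smallest unadjusted p followed until 6 were named, stated as not passing. Predicted genes, receptor variable segments and olfactory or vomeronasal receptors were counted and not named. The second took up to 4 members of each list with the smallest unadjusted p. The third named Foxp3, Cd4, Cd8a, Cd8b1, Cd3e, Ifng, Gzmb, Prf1, Il10, Tgfb1, Ctla4, Il2ra, Ikzf2, Cd40lg and Pdcd1 whatever their values. Foxp3 had no probe set with a single symbol and was not analysed here. The criteria were applied to the arrays numbered 3 and 4 as well, a use chosen after the data were seen. The 1 gene lower on those arrays is not reported here.

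The arrays carry no detection calls in the table used here, so a background line was set for each array after the data were seen. It was the 99th percentile of 1182 probe sets for olfactory and vomeronasal receptors, genes not expected in T cells. By that definition about 1% of silent genes lie above it. The number of arrays limits the precision.

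Arrays with the same number were checked for pairing before the fits were compared. Deviations from the group means of same-numbered arrays correlated, across probe sets, by 0.499, 0.507, 0.410 and 0.599 for numbers 1 to 4. All 4 exceed 0.1, the bound set for treating the numbers as pairs, and the source of the pairing is the data and not the labels. Arrays 1 and 2, or 3 and 4, of opposite groups correlated as much, by 0.497, 0.483, 0.411 and 0.581, so the shared deviation follows the 2 sets of arrays. A fit with the replicate number as a block was an alternative fixed beforehand. The other alternatives were leaving out each array, quantile normalization again, centring on the median, cyclic loess, filters on dim probe sets, other sets of probe sets, trend and robust moderation, array weights, other thresholds, an estimated inter-gene correlation, fry and the mean of a gene's probe sets. Fits of the arrays numbered 3 and 4 alone, of those numbered 1 and 2 alone, with the set as a block, and with the replicate block plus an estimated correlation were added after the data were seen.

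The procedure was tested on simulated data with the real means of each set of arrays, the real spread and 67, 67 and 66 of 21218 probe sets changed by 1, 2 and 3 on the log2 scale, shifted equally on all arrays and independent between probe sets. With all 8 arrays, limma recovered 91.0% of the changes of 1 and 100% of those of 2 and of 3, with 0 false calls. With the arrays numbered 3 and 4 alone it recovered 95.5%, 100% and 100%, with 19 false calls. A list of 24 genes shifted by 1 was called in both designs. A further list, which could share members with it, was also called in each, and 0 lists were called in unchanged data. In unchanged data limma called 0 probe sets with all 8 arrays and 3 with the arrays numbered 3 and 4. On the real arrays numbered 1 and 2 only 2.52% to 5.57% of genes lay above the background line. The simulated recovery with all 8 arrays does not hold for a change that shows only on the arrays numbered 3 and 4.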

Results

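The series compared T cells infiltrating grafts that were being rejected with T cells from grafts in mice made tolerant by antibodies against CD4, CD8 and CD40L, the ligand through which helper T cells activate antigen-presenting cells. The data comprised 8 arrays of CD3-positive cells isolated from the grafts at day 30, 4 from rejecting and 4 from tolerant hosts. Values are log2 RMA values, and differences are tolerant minus rejecting.

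Abundant transcripts separated the arrays into 2 sets that did not follow the groups. Actb, chosen after its values were seen, and B2m are examples. Actb, which encodes cytoplasmic beta-actin, lay between 1.62 and 1.95 on the 4 arrays numbered 1 and 2 of either group, and between 6.54 and 7.82 on the 4 arrays numbered 3 and 4. B2m, the light chain of MHC class I, lay between 0.98 and 2.35 on the former and between 4.69 and 6.44 on the latter. The share of genes above the background line was 4.81% and 5.57% on rejecting arrays 1 and 2 and 2.77% and 2.52% on tolerant arrays 1 and 2. It was 14.3% and 9.12% on rejecting arrays 3 and 4 and 16.3% and 15.9% on tolerant arrays 3 and 4. Across probe sets, arrays numbered 1 and 2 correlated with each other by 0.598 to 0.639 and arrays numbered 3 and 4 by 0.855 to 0.927. Component 1 held 57.1% of the variance and separated these sets. Both sets held 2 rejecting and 2 tolerant arrays, so each comparison is given over all 8 arrays and within each set.

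**Figure D1:**
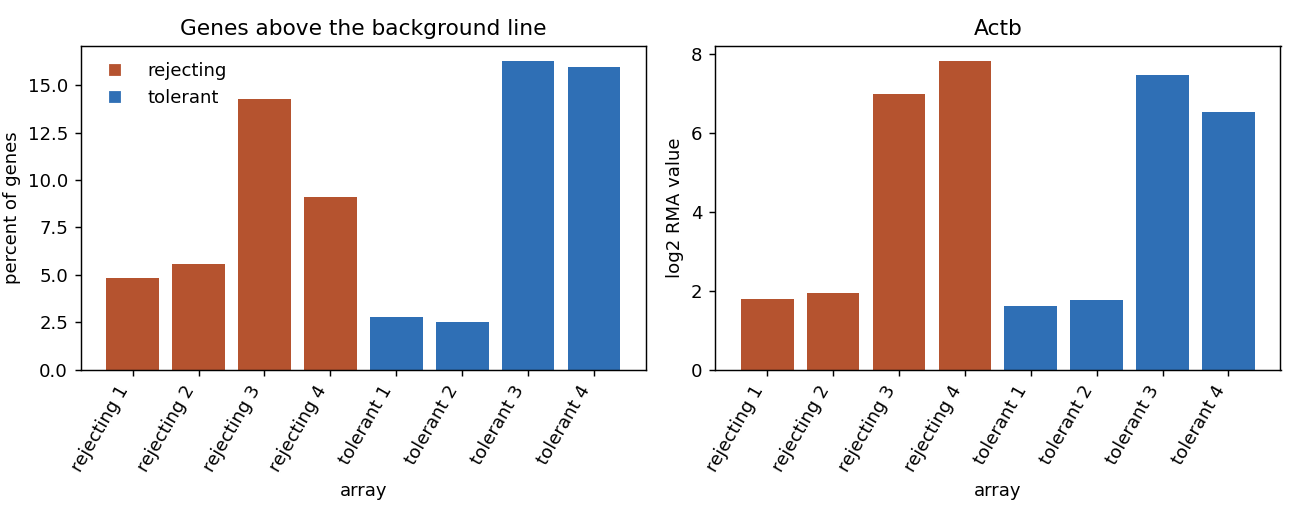
Bars show, for each of the 8 arrays, the percent of genes above that array's background line (left) and the log2 RMA value of Actb (right), coloured by group. The arrays numbered 1 and 2 of both groups lie at 2.52% to 5.57% of genes, below all arrays numbered 3 and 4, at 9.12% to 16.3%.

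Over all 8 arrays, no gene passed the test between tolerant and rejecting T cells. The genes with the smallest unadjusted p differed little in level. Eva1a (probe set 10539238), a regulator of autophagy, averaged 0.44 ± 0.08 (SD, n = 4) in rejecting and 0.89 ± 0.06 (SD, n = 4) in tolerant samples. Slc39a13, a zinc transporter, averaged 1.04 ± 0.10 and 1.44 ± 0.13 (SD, n = 4 each), and Cyp21a1, the steroid 21-hydroxylase, 0.78 ± 0.31 and 1.53 ± 0.33 (SD, n = 4 each). Tuba3a, Tram1 and Avpr1a had differences of 0.42, 0.49 and 0.34. In the other direction, Ifi205 (10360406), an interferon-inducible gene of the p200 family, averaged 0.69 ± 0.09 and 0.10 ± 0.14 (SD, n = 4 each). Hoxa2, Znrd2, Ffar1, Pdcd10 and Gpr17 had differences of -0.54, -0.50, -0.43, -0.40 and -0.34. Each of these 12 genes had an adjusted p of 1 in limma, and only Tuba3a lay above the background line on all 8 arrays. The test called 0 of 21218 probe sets at adjusted p under 0.05. At an unadjusted p under 0.05 there were 613, or 2.89%, against 1061 expected by chance, and 470 probe sets, or 2.22%, had groups that did not overlap, against 2.86% by chance. The count stayed at 0 with the replicate number as a block (1123 at an unadjusted p under 0.05) and with the set of arrays as a block (1187).

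The T cell genes chosen in advance did not pass the test over the 8 arrays, each with a limma adjusted p of 1. Cd3e (10593024), a chain of the T cell receptor complex, averaged 1.49 ± 0.63 in rejecting and 2.05 ± 1.51 in tolerant samples (SD, n = 4 each), a difference of 0.56 with a standard error of 0.66. The coreceptors Cd4, Cd8a and Cd8b1 had differences of 0.05, -0.02 and 0.17. Among effector genes, Gzmb and Prf1, which encode granzyme B and perforin, had differences of -0.20 and 0.12, and Ifng had -0.17. Among genes tied to regulatory T cells and suppression, Il2ra, Ikzf2, Il10 and Tgfb1 had differences of -0.02, 0.03, -0.09 and -0.04. Pdcd1 and Cd40lg had 0.20 and 0.03. Ctla4, an inhibitory receptor, had -0.23 with a standard error of 0.10 and a limma adjusted p of 1. Prf1, Ikzf2, Il10, Il2ra, Cd40lg and Ctla4 lay above the background line on 0 of the 8 arrays. Cd4, Cd8a, Gzmb and Pdcd1 lay above it on 1 array each, Ifng on 2, Tgfb1 on 3, Cd8b1 on 4 and Cd3e on 5. Small differences of genes at background do not show that their expression was unchanged. The lists of pan T cell genes (adjusted p = 0.235), CD4 lineage (adjusted p = 0.915), CD8 lineage (adjusted p = 0.780), cytotoxic effectors (adjusted p = 0.765), Th1 (adjusted p = 0.780), Th2 (adjusted p = 0.651), Th17 (adjusted p = 0.765) and regulatory T cells (adjusted p = 0.349) did not pass in limma's camera. For CD4 lineage, Th1 and Th17 the median, the mean and the test did not share a sign. In these lists, 1 of 6, 2 of 13 and 1 of 11 measured members lay above the background line on at least 2 arrays. In the pan T cell list it was 6 of 18, and Cd3d, Cd247 and Cd28 lay above the line on 0 of the 8 arrays.

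**Figure D2:**
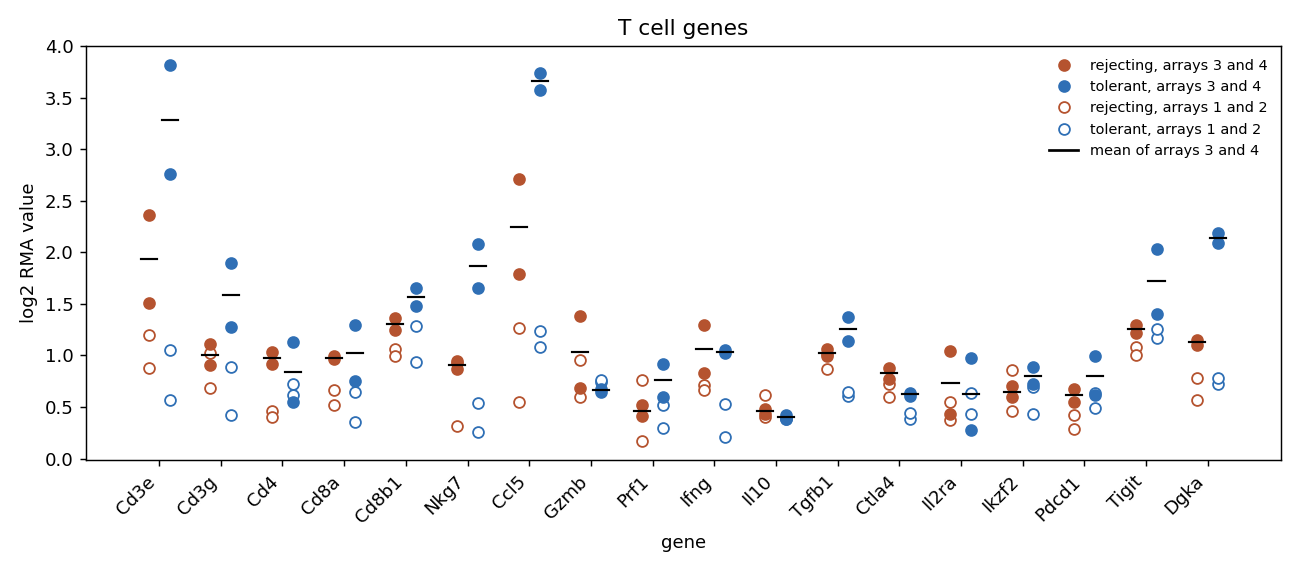
Points show the log2 RMA value of 18 T cell genes on each array, filled for arrays numbered 3 and 4 and open for arrays numbered 1 and 2, coloured by group, with black lines at the mean of the 2 filled points. Cd3e and Ccl5 reach 3.82 and 3.74 on tolerant arrays. Cd4, Cd8a and Gzmb reach at most 1.13, 1.30 and 1.38 on any array. Values of different probe sets are not a measure of relative expression between genes.

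Of 48 gene lists, 4 shifted upward in tolerant samples over all 8 arrays and 0 shifted downward. The type I interferon response list had a median difference of 0.09, with 25 of 30 measured members higher (camera adjusted p = 0.00695). Its Oasl2, Oasl1 and Ifit1 had differences of 0.46, 0.32 and 0.29, and only 5 of the 30 lay above the background line on at least 2 arrays. The kidney tubule list had a median difference of 0.18, with 15 of 17 members higher (adjusted p = 0.00937). The extracellular matrix list had 0.17, with 22 of 29 higher (adjusted p = 0.0277), and the fibroblast list 0.22, with 12 of 14 higher (adjusted p = 0.0481). The matrix and fibroblast lists share Col1a1, Col1a2, Col3a1, Dcn and Lum, so their calls are not independent. Of the members of these 4 lists, 0 passed the test of single genes, over all genes tested and adjusted over the list alone. With an estimated correlation in place of the preset one, 0 of the 48 lists passed, and each of these 4 had an adjusted p = 0.929 with an estimated correlation. The self-contained test fry called 0 lists as well (lowest adjusted p = 0.936). With the replicate number as a block, 7 lists passed, the additional ones being complement (adjusted p = 0.0145), antigen presentation (adjusted p = 0.0385) and NF-kappaB targets (adjusted p = 0.0405), and 0 passed with the block and an estimated correlation. Without tolerant replicate 4, 0 lists passed, and without tolerant replicate 3, 1 list passed, type I interferon response. In the latter fit the median difference went from 0.217 to 0.00431 for fibroblast, from 0.17 to 0.0602 for extracellular matrix and from 0.182 to 0.0505 for kidney tubule markers.

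On the arrays numbered 3 and 4, which carried the signal, 10 probe sets were higher in the 2 tolerant samples and 1 was lower. This comparison of 2 against 2 samples was chosen after the data were seen. Slc12a3 (probe set 10574059), the thiazide-sensitive sodium chloride cotransporter of the distal convoluted tubule of the kidney, was higher by 2.93 with a standard error of 0.19 (limma adjusted p = 0.0359). Its values were 0.58 and 1.08 in rejecting and 3.65 and 3.87 in tolerant samples. The rejecting values lay near or under the background lines of those arrays (1.01 and 1.14), so the size of the difference is not exact. Calb1 (10503416), a calcium-binding protein of the same tubule segment and of neurons, was higher by 1.64, and Wnk1 (10547436), a kinase that regulates sodium chloride cotransport, by 1.71. Sfrp1 (10570957), a secreted inhibitor of Wnt signalling, was higher by 3.15 with a standard error of 0.13 (limma adjusted p = 0.00826). The matrix proteoglycans Bgn (10600169) and Fmod (10349947) were higher by 2.59 and 1.53. Cd81 (10559261), a tetraspanin, was higher by 2.38, and Selenop (10422598), a selenium transport protein, by 2.22. The lysosomal genes Ctsd (10569319) and Laptm4a (10394477) were higher by 1.70 and 1.53. Of the genes added to reach 6 in the lower direction, Snora52, Rbm10, Fau, Foxa1 and Znrd2 had differences of -2.51, -0.87, -0.69, -0.67 and -0.66 and did not pass. Without tolerant replicate 3 or without tolerant replicate 4, 0 probe sets passed, and without rejecting replicate 4, 48 passed. With all 35556 probe sets tested together, 0 passed. With the replicate number as a block, 8 passed, and Calb1, Wnk1, Ctsd, Fmod and Laptm4a did not.

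**Figure D3:**
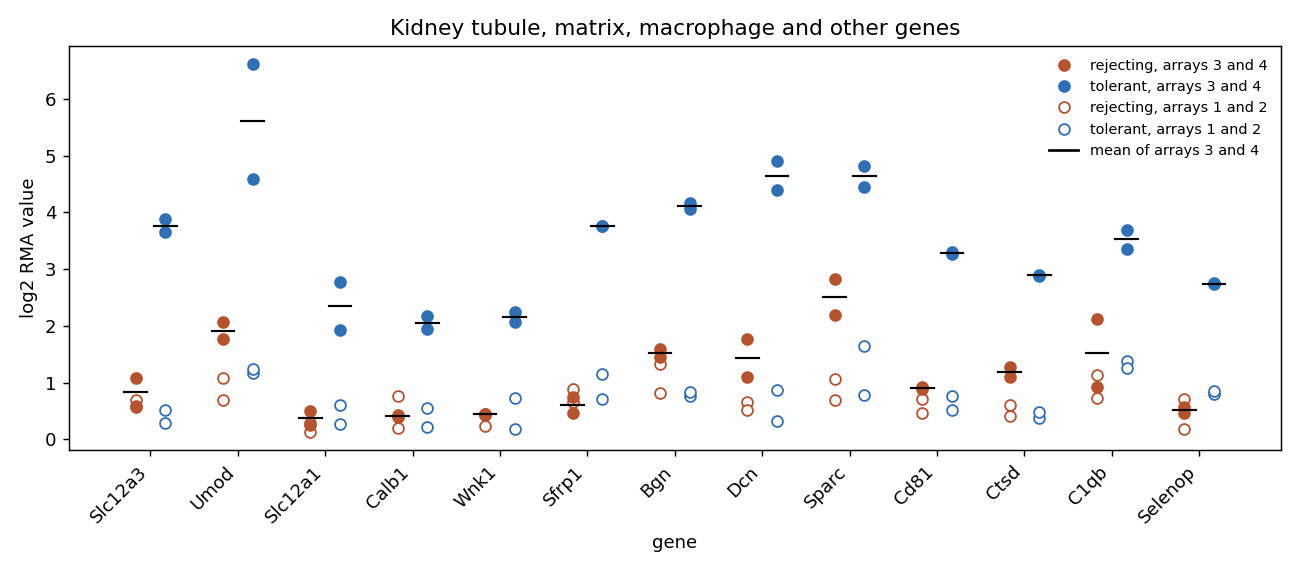
Points show the log2 RMA value of 13 genes on each array, filled for arrays numbered 3 and 4 and open for arrays numbered 1 and 2, coloured by group, with black lines at the mean of the 2 filled points. Slc12a3 reads 3.65 and 3.87 on tolerant arrays 3 and 4 against at most 1.08 on the other 6 arrays.

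Markers of kidney tubule, connective tissue and macrophages were higher together on tolerant arrays 3 and 4 in camera with its preset correlation. With an estimated correlation, 0 of the 48 lists passed on these arrays (lowest adjusted p = 0.683). In the kidney tubule list, 15 of 17 members were higher and 1 passed the test of single genes, or 4 adjusted over the list alone (camera adjusted p = 2.82e-08). Its median of 0.358 went to 0.209 without tolerant replicate 3 and to 0.521 without tolerant replicate 4. Umod, a urinary protein made in the thick ascending limb, read 1.76 and 2.06 in rejecting and 6.61 and 4.59 in tolerant samples (limma adjusted p = 0.226). Slc12a1, the cotransporter of the same segment, had a difference of 1.97 (limma adjusted p = 0.183). In the extracellular matrix list, 24 of 29 were higher and 1 passed, or 10 adjusted over the list alone (adjusted p = 5.06e-10). Dcn and Sparc had differences of 3.21 and 2.12 and did not pass on their own. The fibroblast list had 13 of 14 higher and 0 passing, or 7 adjusted over the list alone (adjusted p = 6.98e-08). In the macrophage and monocyte list, 18 of 24 were higher and 1 passed, or 6 adjusted over the list alone (adjusted p = 2.12e-04). Lyz2, C1qb and Ctsl there had differences of 2.40, 2.00 and 1.10. Endothelial cell (adjusted p = 0.00339) and epithelial cell markers (adjusted p = 0.0264) also shifted upward, with differences of 1.25 for Emcn and 0.70 for Krt7. The epithelial call was lost without rejecting replicate 3 (adjusted p = 0.204) and without tolerant replicate 3 (0.403).

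Of the gene programmes on these 4 arrays, 6 shifted upward besides extracellular matrix, each with an adjusted p = 0.683 with an estimated correlation. Complement genes had 9 of 12 members higher (camera adjusted p = 0.00152), with a difference of 2.38 for Serping1, the C1 inhibitor. Antigen presentation genes had 15 of 20 higher (adjusted p = 0.00152), with differences of 1.43 for B2m and 1.13 for H2-K1. Type I interferon response genes had 25 of 30 higher (adjusted p = 0.00152). Oxidative phosphorylation genes had 25 of 29 higher (adjusted p = 1.56e-04), with differences of 0.98 for Ndufs7 and 0.80 for Atp5c1. Glycolysis and hypoxia genes had 16 of 24 higher (adjusted p = 0.0155), with differences of 0.86 for Ndrg1 and 0.77 for Aldoa. Inhibitory receptor and anergy genes had 17 of 24 higher (adjusted p = 0.0286). There Dgka, a diacylglycerol kinase that limits T cell receptor signalling, had a difference of 1.02 and Tigit of 0.46, and Ndrg1 belongs to this list too. Other receptors of the list went both ways. Lag3, Pdcd1, Cd160 and Cd244a had differences of 0.26, 0.19, 0.17 and 0.05, and Ctla4, Btla and Havcr2 had -0.21, -0.21 and -0.13. In each of these 6 programmes 0 members passed over all genes tested. Members above the background line on all 4 arrays numbered 0 for complement and for type I interferon response and 3 for inhibitory receptors and anergy. They numbered 9 for antigen presentation, 10 for oxidative phosphorylation and 8 for glycolysis and hypoxia. Adjusted over the list alone, 3 passed for complement, 3 for antigen presentation, 2 for glycolysis and hypoxia, 2 for inhibitory receptors and anergy and 0 for the other 2. Each of the 6 calls was lost when 1 array was left out. Without tolerant replicate 4, type I interferon (adjusted p = 0.607), complement (0.121) and inhibitory receptors (0.605) did not pass. Without rejecting replicate 3, glycolysis (0.618), oxidative phosphorylation (0.128) and inhibitory receptors (0.0666) did not pass. Without rejecting replicate 4, antigen presentation (0.572, with its median going from 0.304 to 0.035) and inhibitory receptors (0.11) did not pass, and without tolerant replicate 3 glycolysis (0.142) did not.

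Within the same 4 arrays, the T cell genes named here did not pass the test over all genes. Cd3e read 1.51 and 2.36 in rejecting and 2.76 and 3.82 in tolerant samples, a difference of 1.36 with a standard error of 0.42 (limma adjusted p = 0.572). Ccl5 and Nkg7, expressed by cytotoxic lymphocytes, had differences of 1.41 and 0.96. Cd8b1, Gzmb, Ifng and Tgfb1 had 0.26, -0.37, -0.03 and 0.23. The cytotoxic effector list had a median difference of 0.07 (adjusted p = 0.174), and the regulatory T cell list one of 0.01 (adjusted p = 0.364). Leaving out tolerant replicate 3 left 1 tolerant array. The medians of the cytotoxic effector, regulatory T cell and pan T cell lists were then 0.131, 0.194 and 0.0864. On all 4 arrays they were 0.0741, 0.0138 and 0.0825. With the replicate number as a block, the pan T cell list passed as higher (adjusted p = 0.0486). On all 4 arrays without the block, the pan T cell and cytotoxic effector lists had an adjusted p = 0.683 with an estimated correlation, and the regulatory T cell list 0.843. Adjusted over the list alone, 1 member each passed in the cytotoxic effector, CD8 lineage, gamma-delta T cell and Th17 lists. The cytotoxic effector and CD8 lineage lists shared that member, Nkg7. It was Tmem176b in the gamma-delta T cell list and Stat3 in the Th17 list.

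On the arrays numbered 1 and 2, 0 probe sets passed (1093 at an unadjusted p under 0.05) and 0 of 48 lists passed, the lowest adjusted p being 0.962. The difference between the sets was tested as an interaction in limma, which called 12 probe sets. Only 2.52% to 5.57% of genes lay above background on the arrays numbered 1 and 2. The interaction therefore cannot tell an absent difference on those arrays from an absent signal. Slc12a3, Sfrp1, Bgn and Cd81 had an interaction adjusted p of 0.00543 each, and Ctsd had one of 0.0163. Among lists, 7 differed between the sets, including extracellular matrix (interaction adjusted p = 5.24e-07), kidney tubule (5.82e-07) and macrophage markers (1.52e-04), and 0 did with an estimated correlation (lowest adjusted p = 0.454).

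**Figure D4:**
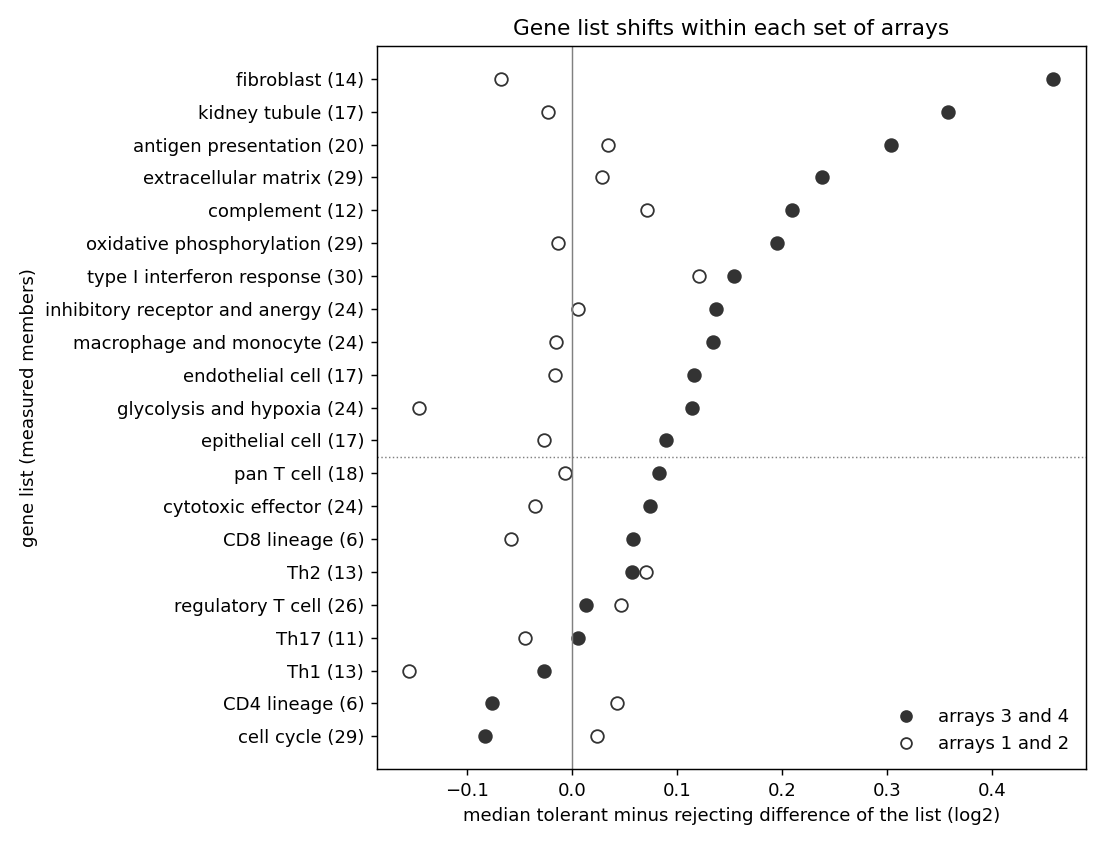
Points show the median tolerant minus rejecting difference (log2) of 21 gene lists within arrays numbered 3 and 4 (filled) and within arrays numbered 1 and 2 (open), with measured members in brackets. The 12 lists above the dotted line passed camera on arrays 3 and 4, where fibroblast (0.46) and kidney tubule (0.36) markers had the highest medians, and 0 lists passed on arrays 1 and 2.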

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

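The tests of array signal, of histones and of other splits of the samples, or the criteria used in them, were chosen after the results were seen. An earlier test of a higher signal, the median of 0.0405 below against bounds set before it was seen, did not decide, and the kidney segment lists were written after the kidney list had been seen but before their own values were.

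Kidney tubule genes were higher on tolerant arrays 3 and 4, although the isolation of CD3-positive cells would be expected to remove tubule cells. Quantile normalization of the 4 arrays took the median difference of 1227 genes above background on all 4 from 0.0405 to -0.00761. It left the kidney list at 0.299 against 0.358 before, still past the threshold at camera's preset correlation. With an estimated correlation the list had not passed as deposited. The general difference to be removed was small beside that of the kidney list, so the list could hardly have fallen far. The values show only that the general difference was the smaller of them. The test does not decide whether a generally higher signal was part of the source. RNA of distal tubule may be present. Of 28 listed distal genes, 24 were measured, with a median difference of 0.179, at the 99.6 percentile of matched random lists. Hsd11b2 was at 2.32 and Defb1 at 1.56, sizes that are not exact. Defb1 lay below background on rejecting arrays 3 and 4, and Hsd11b2 on rejecting array 4. The 23 measured proximal genes lay at the 60.7 percentile, and the abundant Kap, Lrp2 and Cubn stayed at background on all 8 arrays. Only 2 of the 23 lay above background on at least 2 of arrays 3 and 4, against 12 of the 24 distal genes. Their median differences were 0.331 and 0.6. The proximal percentile therefore rests mostly on genes near background, and the 2 percentiles are not a like comparison. Random lists were drawn gene by gene, so the percentiles measure spread between genes and not between samples. Kidney genes can vary together (estimated correlation 0.37 in the kidney tubule list over all 8 arrays), so the percentiles do not decide. The labels used here do not state the graft site, so host kidney carried over at dissection was not tested. Cross-hybridising human graft RNA and a biological effect of tolerance were not tested either and stay open.

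Low signal on the arrays numbered 1 and 2 occurred in both groups. Across the same 1227 genes the means of the 2 sets had a Spearman correlation of 0.499, where genes are not independent replicates. Genes above background on none of the 8 arrays, 14002 in number, gave 0.609, so this correlation does not decide whether little labelled target was the source. Damaged RNA, few cells and a processing batch were not tested, and no biological explanation was tested.

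Histone probe sets that list several symbols, which the comparisons of single genes leave out, had a median difference of -1.92 on arrays 3 and 4, with 38 of 38 lower in tolerant samples, and of -0.516 on arrays 1 and 2, with 37 of 38 lower, while 44 histone probe sets with 1 symbol had medians of -0.136 (34 lower) and -0.0467 (26 lower). An exact permutation within sets, 2-sided, gave p = 0.0556 for the former, the smallest it allows, and p = 0.111 for the latter, and the medians of the former kept their direction under quantile normalization (-1.07 on arrays 3 and 4), median centring and cyclic loess (-0.148 on arrays 1 and 2). Fewer dividing cells cannot be told apart from no change in division, because only 4 cell cycle genes lay above background, with a median difference of -0.207. A lower yield of RNA without a poly(A) tail stays open too, because 28 small RNA probe sets had a median of -0.872, with 24 lower, but 11 of them were for Rnu2-10, and their mean was 4.53 on rejecting array 3 against 2.81 on tolerant array 3, and 3.01 on rejecting array 4 against 3.28 on tolerant array 4. A biological effect of tolerance on these cells was not excluded.

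In 5 of 162 groups of 4 samples examined, 1 sample lay far from the others, where chance gives about 5% if the 4 samples are alike. Each group joined 2 arrays of low signal and 2 of higher signal, so the count cannot be set against that rate. The outlying values below were all on arrays numbered 1 and 2, under their background lines of 1.15 to 1.35. Eva1a was 0.563 on rejecting array 1, against 0.386 to 0.409 on the other rejecting arrays. Wnk1 was 0.245 on rejecting array 2, against 0.43 to 0.452. Nkg7 was 0.313 on the same array, against 0.87 to 0.942. Avpr1a was 0.779 on tolerant array 2, against 0.55 to 0.576. Cyp21a1 was 1.04 on tolerant array 1, against 1.66 to 1.74.

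Of the 35 splits of the 8 arrays into 4 and 4, all 35 had to give as many changed probe sets as the real 0, so this count says nothing about chance. The highest was 1539, in the split of the arrays numbered 1 and 2 against those numbered 3 and 4, which points to a structure of the samples. For gene lists, 16 of the 35 splits gave at least the real 4, with 12 as the highest other, so chance was not excluded. With the replicate block, 3 of 8 splits gave at least the real 7, with 9 as the highest other, and the splits are too few for a share under 0.05. On arrays 3 and 4 there are 3 splits, too few as well. There 1 split gave the real 11 changed probe sets, with 0 as the highest other, and 1 gave the real 12 lists, with 8 as the highest other.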

How the results depend on the processing

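The fits of subsets of arrays, the block by set of arrays and the replicate block with an estimated correlation were chosen after seeing the data. Over all 8 arrays the count of changed probe sets was 0 under every alternative run, except on arrays 3 and 4 alone, where 10 were higher and 1 lower, 11 in all. The 4 gene lists became 7 with the replicate block, 0 with that block and an estimated correlation, 8 with the set of arrays as a block, 12 on arrays 3 and 4, 0 on arrays 1 and 2, 2 with quantile normalization again, 10 with array weights, 0 with an estimated correlation and 0 with fry. Leaving out 1 array gave 0 lists (without tolerant replicate 4) to 11 (without tolerant replicate 1), with 1 without tolerant replicate 3, 2 without rejecting replicate 1 or 2, 7 without rejecting replicate 3 and 10 without tolerant replicate 2. Over all 8 arrays the fibroblast call was lost without each array except rejecting replicate 3 and tolerant replicates 1 and 2, with quantile normalization and with the filter on the mean. The matrix call was lost without rejecting replicate 1 (median from 0.17 to 0.0899) or 2 (0.103), without tolerant replicate 3 (0.0602) or 4 (0.0623) and with quantile normalization. On arrays 1 and 2, the extracellular matrix list reversed in its test (median 0.0283), as did the fibroblast list (-0.0671). On arrays 3 and 4, the 11 changed probe sets became 17 with a filter on the mean, 0 with the whole table, 38 with 1 probe set per gene, 26 with trend and robust moderation and 25 at an adjusted p under 0.10. Leaving out 1 array there gave 0 (without tolerant replicate 3 or 4) to 48 (without rejecting replicate 4), with the lone sample assumed to vary like the other group. The 12 lists became 0 with an estimated correlation, 0 with fry, 14 with the replicate block (pan T cell and TGF-beta signalling added) and 9 to 14 when 1 array was left out. The kidney tubule, matrix, fibroblast, macrophage and endothelial lists passed in all 4 of these fits, and the other 7 did not. The inhibitory receptor list was also lost with quantile normalization, cyclic loess, the filter on the mean and trend and robust moderation, the epithelial list with cyclic loess and both filters, and the glycolysis list with the filter on a percentile and trend and robust moderation. Apart from the larger number of tests with the whole table and the looser threshold, the cause was not tested. Among single genes, 53 of 1670 values over all 8 arrays and 6 of 1081 on arrays 3 and 4 changed direction, and among lists 105 of 1193 and 38 of 762. Array weights were not run for arrays 3 and 4. Signal over background limits all of this, since 2.52% to 5.57% of genes lay above the background line on the arrays numbered 1 and 2.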

Other observations

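Over all 8 arrays, lists of other blood cells did not pass in camera. B cell (adjusted p = 0.432), NK cell (0.349), neutrophil (0.891), dendritic cell (0.98) and erythroid (0.98) markers had median differences of -0.04, -0.10, -0.01, 0.01 and -0.02. The interferon-gamma response list had 6 of 17 members higher and a median difference of -0.02 (adjusted p = 0.78). The 4 measured sex-linked genes, too few to test as a list, had a median difference of -0.0661, with 0 passing on their own. Cell cycle genes had 12 of 29 members higher over all 8 arrays (adjusted p = 0.734) and 8 of 29 higher on arrays 3 and 4 (adjusted p = 0.11). Without rejecting replicate 3, which left 1 rejecting array, the median of the cell cycle list on arrays 3 and 4 went from -0.0824 to -0.116.

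Among the probe sets outside those with 1 symbol, limma called 0 of 1881 with several symbols and 0 of 12457 with none listed, over all 8 arrays, with the replicate block and on arrays 3 and 4.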
